A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

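Transcript levels were measured in 3 strains of the budding yeast Saccharomyces cerevisiae, all described as grown without iron: CM3260 (wt), Y18 (aft1), and a strain labelled as Y18 with an AFT2 deletion (aft1aft2). Aft1 and Aft2 are transcription factors that switch on iron uptake genes when iron is scarce. Per the labels, total RNA was extracted with hot phenol from exponentially growing cells. Copies made from 5 µg of RNA were hybridised to nylon GeneFilters membranes, which carry spots of yeast DNA. The membranes were read with a phosphor screen after 3 days and quantified with the PATHWAYS 3 software. The genome build and annotation behind the spots are not given in the sources used here.

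The 6 samples are 3 comparisons of strains, each in experiments 1 and 2. The authors deposited 1 log ratio per spot and sample, taken here as log2 because the base of the logarithm was not stated. With another base the folds would change and the directions would not. How the authors normalised membranes, and which strain stood on top of the ratio, was not stated either. The ratio was taken as the first-named strain over the second, which is likely from the order in the titles and from the uptake genes that textbook knowledge places under Aft1. Each ratio was then turned to mutant minus reference. Were the order the other way round, every change below would have the opposite sign and the same size.

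The table held 6084 spots with no missing values, and 0 columns were left unused. The platform table paired 5523 spots with 1 gene symbol, 0 with several and 561 with none. These gave 5490 symbols, of which 32 stood on more than 1 spot. Symbols were updated through the gene table of the R64 assembly, in which 100% of the named spots had a match. No coordinates are printed, because the build used for the membranes is unknown.

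The deposited columns were not centred. Turned to mutant minus reference, their medians in experiments 1 and 2 were 0.31 and 0.22 for aft1 against wt, 0.40 and 0.625 for aft1aft2 against wt, and 0.09 and 0.42 for aft1aft2 against aft1. Each column was centred on its median, so every change is relative to the typical spot of its column. The ratio of aft1aft2 to wt equalled the sum of the other 2 log ratios within 0.01 at all 6084 spots in both experiments. The 3 ratios of an experiment therefore came from 3 shared hybridisations, 6 in all, and carry 2 independent columns per experiment. The rule set for this case was followed: strain levels were estimated from the ratios by least squares, and limma 3.58.1 in R 4.3.3 fitted strain and experiment, with 2 residual degrees of freedom. The empirical Bayes prior had 4.25 degrees of freedom and a variance of 0.0754. The tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all spots, and the threshold was an adjusted p of 0.05. Errors are standard errors from this fit with n = 2 hybridisations per strain. The labels say that hybridisations were done in duplicate and do not say that the experiments were separate cultures, so p-values measure the spread between these samples, which may be technical.

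Gene lists fixed before the data were examined were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01, over the 26 lists that had at least 5 spots. Adjustment covered these lists in the 3 comparisons together. The same lists were tested with an estimated correlation and with fry, which asks if a list's genes move one way on balance without comparing them with other genes. Camera called 10, 7 and 9 of the 26 lists in aft1 against wt, aft1aft2 against wt and aft1aft2 against aft1. With an estimated correlation it called 0, 0 and 0, with a smallest adjusted p of 0.299, while 3, 3 and 2 lists had an unadjusted p under 0.05. In that setting camera uses the 2 residual degrees of freedom, so hardly any list could pass after adjustment. A lost call therefore does not show that correlation between genes explains a shift. Stress genes in aft1 against wt had an estimated correlation of -0.03, yet their camera unadjusted p went from 5.98e-12 to 0.0167. Estimates for other lists lay on both sides of the preset 0.01. They reached 0.192 for glycolysis, 0.174 for reductive uptake and 0.082 for ribosomal proteins. For lists above the preset, the camera p-values with the preset correlation may be too small. Fry called 9, 9 and 7.

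The fit was tested on simulated data modelled on aft1 against wt with 6084 spots. It recovered 38% of changes of log2 1, 98% of changes of log2 2, and 100% of changes of log2 3 and of log2 4. There were 14 false calls, and 3 calls in the comparison simulated without change. Camera with the preset correlation called the 1 simulated list of 20 genes shifted by log2 1 and 0 of 50 unshifted lists. The simulated genes varied independently of each other, so this does not test the preset for lists of correlated genes. With an estimated correlation the shifted list had an unadjusted p of 0.00952 and an adjusted p of 0.485, so that setting missed a simulated shift after adjustment.

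The genes named were set by rule before the data were examined: AFT1 and AFT2; the 2 to 4 members with the largest change in each of 4 iron lists; the 10 genes with the largest change per direction among those past the test with the same sign in both experiments; and strain markers as values. Other list members are named to show what a count holds, and were chosen after their values were seen. Chance correlation between comparisons that share hybridisations was simulated with 100 draws, as was the overlap of lists of the observed sizes, taken by smallest p per direction. Alternatives were the values as deposited, scaling and quantile normalisation of columns, the 2 columns of a comparison alone, experiment as a block, a robust prior, an adjusted p of 0.1, and each replicate left out. Fitting the 6 columns as if independent and leaving out single hybridisations, and the scalings for gene lists, were chosen after seeing the data. Figures were drawn with matplotlib. Precision is limited by the number of membranes, and the signal over background of a spot is not in the values used here.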

Results

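Log ratios for 6084 spots were available for 3 comparisons of yeast strains, each measured in 2 experiments, which makes 6 samples. The strains were labelled as a wild type (wt), an aft1 mutant and an aft1 mutant with an AFT2 deletion (aft1aft2), all described as without iron. By their labels the comparisons ask which transcripts differ with Aft1, and which with Aft2 where Aft1 is mutated. Values are log2 ratios centred on the median of their column, given as mean ± SE from the limma fit. Their direction is likely rather than stated. Between experiments the ratios correlated across spots, which are not independent replicates, with r = 0.553 (rho = 0.459) for aft1 against wt, 0.449 (0.349) for aft1aft2 against wt and 0.554 (0.486) for aft1aft2 against aft1.

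The spots of the mutated genes showed no loss of transcript that passed the test. The AFT1 spot stood at 0.03 ± 0.25 (SE, n = 2) in aft1 against wt and at -0.59 ± 0.25 in aft1aft2 against wt, with limma adjusted p-values of 0.970 and 0.243. The AFT2 spot stood at -0.33 ± 0.54 in aft1 against wt. In aft1aft2 against wt AFT2 was -0.40 in experiment 1 and 1.96 in experiment 2 (mean 0.78 ± 0.54, adjusted p = 0.441), where a deletion would lower it. In aft1aft2 against aft1 AFT1 was -0.62 ± 0.25 and AFT2 1.11 ± 0.54, neither past the test (adjusted p = 0.213 and 0.286). Which part of either gene was removed, and which part the spots read, are not given in the sources used here. The spots therefore do not check the strain labels, and below aft1 and aft1aft2 mean the hybridisations labelled so. Of the strain markers, LEU2 passed the test in aft1 against wt at 2.21 ± 0.28 (adjusted p = 0.0265). TRP1 was 1.76 ± 0.31 in aft1 and 1.38 ± 0.31 in aft1aft2 against wt, neither past the test (adjusted p = 0.0648 and 0.0672). The other markers LYS2, GCN4, URA3 and HIS3 lay between -0.31 and -0.03 in aft1 against wt, while MET17 was 0.64 ± 0.28 and ADE2 1.46 ± 0.43, none of these 6 past the test.

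In the strain labelled aft1, several genes for taking up iron from siderophores fell against wt, as did FET3 and FRE1 of reductive uptake. The direction of the ratios was chosen partly from uptake genes, so that they fell was an input. Only the sizes, and the directions of other genes relative to them, are results. FIT2, which encodes a cell wall mannoprotein that retains siderophore iron, fell furthest of all named spots, to -5.85 ± 0.24 (SE, n = 2), or 57.6-fold. FIT3, of the same family, was -3.37 ± 0.29, the multicopper oxidase gene FET3 -3.43 ± 0.25 and the ferric reductase gene FRE1 -2.03 ± 0.25. The siderophore transporter genes ARN2 and SIT1 were -2.56 ± 0.25 and -2.06 ± 0.28. In the other direction, the membrane protein gene IZH4 rose to 3.98 ± 0.25 and the fatty acid desaturase gene OLE1 to 3.51 ± 0.25.

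Of the 9 siderophore and mannoprotein genes 4 fell, and 6 did when p-values were adjusted over the list alone, while 0 rose. Camera put this list below other genes with a median of -1.93 and an adjusted p of 1.07e-07 (adjusted p = 0.299 with an estimated correlation). Of the 6 reductive uptake genes 2 fell, also 2 adjusted over the list alone. Their median was -0.49, with a camera adjusted p of 0.0045 (adjusted p = 0.408 with an estimated correlation). The largest of the others here were FRE2 at -0.66 ± 0.42 and CCC2 at -0.32 ± 0.49, and the permease gene FTR1 was -0.10 ± 0.29, none past the test. None of the 13 genes of vacuolar and intracellular iron transport and use passed limma's test, against 3 higher and 1 lower at an unadjusted p under 0.05 and 2 higher adjusted over the list alone. Camera did not call this list (median 0.53, adjusted p = 0.0522, and adjusted p = 0.404 with an estimated correlation), but did with columns scaled (adjusted p = 0.0331) or quantile normalised (adjusted p = 0.0401), settings added for lists after seeing the data. Among them MRS4 was 1.66 ± 0.33, ISU2 1.54 ± 0.35, ISU1 0.83 ± 0.35 and SMF3 0.78 ± 0.27. Of 11 other genes known as Aft1 or Aft2 targets 0 passed, against 5 higher at an unadjusted p under 0.05 and 5 adjusted over the list alone. Their list had a median of 0.52 and a camera adjusted p of 0.0411. That list call was lost with an estimated correlation (adjusted p = 0.398) and with the values as deposited (adjusted p = 0.0931), where the median was 0.79. Without replicate 1 it was 0.34. ECM4 at 1.52 ± 0.40, BNA2 at 1.30 ± 0.27, APE1 at 1.21 ± 0.27 and YHB1 at 0.87 ± 0.24 led it.

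Beyond iron, the copper metallothionein spots CUP1-2 and CUP1-1, near-identical copies that a membrane cannot separate, rose to 2.61 ± 0.23 and 2.15 ± 0.24, while the copper transporter gene CTR1 fell to -1.84 ± 0.23. The other large rises were PBI1 at 2.63 ± 0.23, the thioredoxin peroxidase gene TSA2 at 2.49 ± 0.32 and YGL039W at 2.37 ± 0.29. They were followed by TMA10 at 2.22 ± 0.26, LEU2 at 2.21 ± 0.28 and the trehalose synthesis gene TSL1 at 2.12 ± 0.24. The other large falls were SRP40 at -4.67 ± 0.24, the cell wall sensor gene MTL1 at -4.47 ± 0.25, OSW7 at -3.63 ± 0.24, RFM1 at -3.54 ± 0.28 and the glucan synthase gene GSC2 at -3.38 ± 0.26. The paralogues VEL1 and YOR387C stood at -3.66 ± 0.39 and -3.26 ± 0.42, and may share signal. Whether the spots of FIT2, FIT3, SRP40, MTL1 and RFM1 also read sequence shared with other transcripts was not examined here.

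Genes induced by environmental stress lay above other genes, with a median of 1.03 over 24 spots and a camera adjusted p of 9.33e-11 (adjusted p = 0.299 with an estimated correlation). Of these 4 rose, HXK1, HSP104, TPS2 and TSL1, and 15 did adjusted over the list alone. Of 23 ergosterol synthesis genes 3 rose, ERG3, ERG25 and ERG5 at 1.76 to 1.96, and 12 did adjusted over the list alone. Their median was 0.72, with a camera adjusted p of 5.82e-07 (adjusted p = 0.299 with an estimated correlation). The tricarboxylic acid cycle list had a median of 0.64 over 14 spots and 1 rise, IDH2 at 2.05 ± 0.24 (camera adjusted p = 0.00163, and adjusted p = 0.299 with an estimated correlation). Ribosomal protein genes lay lower, with a median of -0.89 over 33 spots. Of these 2 fell, RPS22A and RPL25, and 25 did adjusted over the list alone (camera adjusted p = 7.41e-17, and adjusted p = 0.299 with an estimated correlation). The 10 histone spots had a median of -0.67 with 0 past limma's test and 4 lower adjusted over the list alone (camera adjusted p = 0.000275, and adjusted p = 0.299 with an estimated correlation). Of 10 genes of the zinc regulon 2 fell, ZPS1 at -2.85 ± 0.23 and ADH4 at -2.18 ± 0.29. The zinc list had a median of -0.53 and a camera adjusted p of 0.0352 (adjusted p = 0.393 with an estimated correlation), and the call was lost with columns scaled (adjusted p = 0.0591). With the values as deposited the medians were nearer 0 for zinc at -0.27, reductive uptake at -0.23 and histones at -0.41, and without replicate 2 the histone median was -1.03. Without centring every median of this comparison moves up by the same amount. Camera called these lists as deposited too (adjusted p = 0.00651 for zinc, 0.000817 for reductive uptake and 6.33e-05 for histones). Of the 4 marker genes of the alpha mating type 1 fell, SAG1 at -1.85 ± 0.25, and of the 7 a-mating-type markers 0 passed.

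In total 89 spots passed limma's test in aft1 against wt, 51 higher and 38 lower, of which 3 had no gene name, and 939 had an unadjusted p under 0.05. At least 2-fold in both experiments, without a test, were 239 spots, 117 higher and 122 lower, beside 7 that went opposite ways. As deposited these were 306, 253 higher and 53 lower. With the values as deposited the calls were 58, 44 higher and 14 lower. In that setting FRE1, SIT1, LEU2, VEL1 and YOR387C no longer passed (adjusted p = 0.0627, 0.0545, 0.0506, 0.0511 and 0.0615). With 1 hybridisation left out the calls were 7 without aft1 replicate 1, 4 without aft1 replicate 2, 48 and 38 without wt replicate 1 or 2, and 233 without either aft1aft2 replicate.

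**Figure D1:**
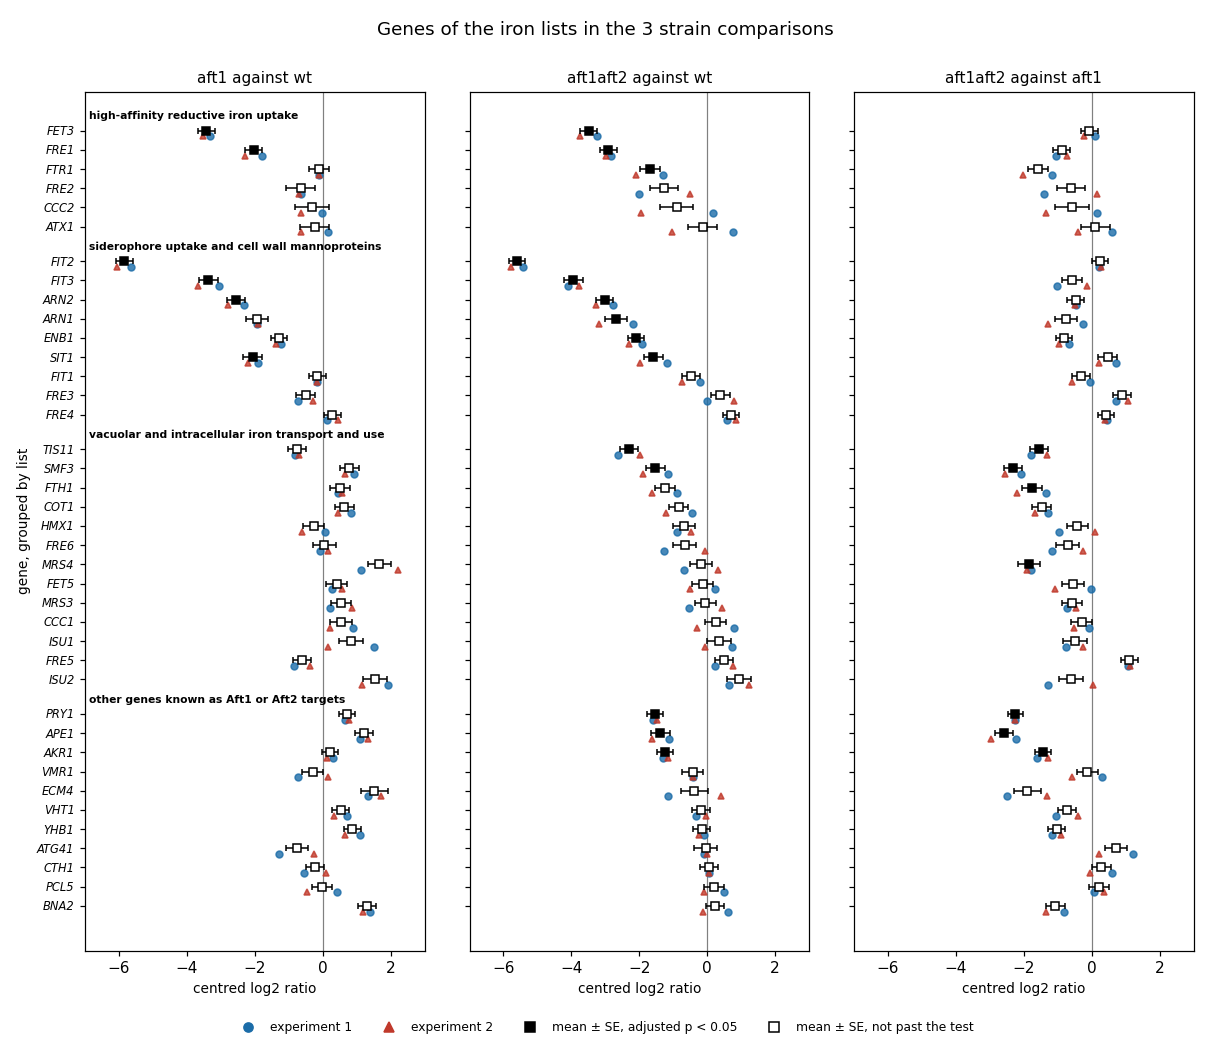
Centred log2 ratio (x axis) of the 39 spots of the 4 iron lists (y axis) in the 3 comparisons, with experiments 1 and 2 as circles and triangles just below the mean ± SE of the fit as squares, filled where the limma adjusted p was under 0.05. FIT2, FIT3 and FET3 lie far to the left against wt in both mutants. In aft1aft2 against aft1 they lie at 0.25, -0.57 and -0.06, while SMF3 at -2.31 and APE1 at -2.59 lie furthest left.

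In the strain labelled aft1aft2, uptake genes that were low in aft1 were low against wt again, and glycolytic genes fell too. FIT2 was -5.60 ± 0.24 (SE, n = 2), FIT3 -3.94 ± 0.29, FET3 -3.49 ± 0.25, FRE1 -2.92 ± 0.25, ARN2 -3.02 ± 0.25 and SIT1 -1.59 ± 0.28. Genes that had not passed in aft1 against wt fell here: the siderophore transporter genes ARN1 at -2.70 ± 0.32 and ENB1 at -2.11 ± 0.24, and FTR1 at -1.69 ± 0.29. For these 3 the direct test between the mutants did not pass. TIS11, whose product binds and destabilises transcripts of iron-using proteins, fell to -2.30 ± 0.26, and the vacuolar metal transporter gene SMF3 to -1.53 ± 0.27. Of 18 glycolytic genes 11 fell, from TDH1 at -3.73 ± 0.25, ENO1 at -2.81 ± 0.29 and FBA1 at -2.62 ± 0.24 to GPM1 at -1.51 ± 0.23.

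Of the 9 siderophore and mannoprotein genes 6 fell and 0 rose, against 6 lower and 1 higher adjusted over the list alone. Their median was -2.11, with a camera adjusted p of 2.77e-05 (adjusted p = 0.299 with an estimated correlation). Of the 6 reductive uptake genes 3 fell, and 4 did adjusted over the list alone. The median of these genes was -1.48, with a camera adjusted p of 0.00023 (adjusted p = 0.356 with an estimated correlation). FRE2 stood at -1.27 ± 0.42 and did not pass. Of the 13 vacuolar and intracellular genes 2 fell, and 3 did adjusted over the list alone, while FTH1 at -1.26 ± 0.29 and ISU2 at 0.93 ± 0.35 did not pass. Camera did not call that list at a median of -0.18 (adjusted p = 0.132), but did with the values as deposited (adjusted p = 0.0431). The median was then 0.34, as all medians of the comparison move up alike without centring. With an estimated correlation the centred values gave an adjusted p of 0.458. Of the 11 other known targets 3 fell, the cell wall protein gene PRY1 at -1.54 ± 0.23, the vacuolar aminopeptidase gene APE1 at -1.38 ± 0.27 and the palmitoyltransferase gene AKR1 at -1.23 ± 0.24, also 3 adjusted over the list alone. VMR1 was -0.43 ± 0.30 without passing, and camera did not call the list (median -0.20, or 0.32 with the values as deposited, adjusted p = 0.0909).

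The glycolysis list had a median of -1.52, with 14 lower adjusted over the list alone and a camera adjusted p of 1.35e-11 (adjusted p = 0.299 with an estimated correlation). TDH1 to TDH3 and the ENO1 and ENO2 pair are closely similar in sequence, so their spots may read each other's transcripts. Of 10 zinc regulon genes 5 fell, ZPS1 at -4.96 ± 0.23, the zinc transporter genes ZRT3 at -3.11 ± 0.24 and ZRT1 at -2.82 ± 0.23, ADH4 at -2.31 ± 0.29 and MCD4 at -1.70 ± 0.25. Adjusted over the list alone 6 were lower and 1 higher. Their median was -1.54 with a camera adjusted p of 3.59e-05 (adjusted p = 0.299 with an estimated correlation). Ribosomal protein genes had a median of -0.92 with 8 of 33 lower, led by RPL16A at -2.05 ± 0.26, and 22 lower adjusted over the list alone (camera adjusted p = 1.1e-12, and adjusted p = 0.299 with an estimated correlation). Of 34 genes of amino acid synthesis under Gcn4 5 fell, among them LYS20 at -2.20 ± 0.23 and LYS9 at -1.79 ± 0.27, and 8 did adjusted over the list alone. Their median was -0.52 (camera adjusted p = 5.02e-05, and adjusted p = 0.299 with an estimated correlation) and -0.0025 with the values as deposited, or -0.32 without replicate 1. The histone list had a median of -0.72 with 1 fall, HTB2 at -1.41 ± 0.24, and 5 adjusted over the list alone (camera adjusted p = 0.00163, and adjusted p = 0.299 with an estimated correlation). The 24 stress genes had a median of 0.09, with 4 higher and 1 lower, and camera did not call them (adjusted p = 0.331). With the values as deposited the medians were nearer 0: -0.97 for reductive uptake, -1.01 for glycolysis, -1.03 for zinc, -0.41 for ribosomal proteins and -0.21 for histones. Without centring every median of this comparison moves up by the same amount, which is no weakening against other spots. Camera called these lists as deposited too (adjusted p = 4.49e-07, 3.54e-17, 5.87e-08, 5.94e-15 and 0.000466, in that order). The stress median moved away from 0, to 0.61.

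Among the largest rises against wt were again IZH4 at 3.02 ± 0.25 and CUP1-2 and CUP1-1 at 2.27 ± 0.23 and 1.84 ± 0.24, with RSC30, which lies next to the CUP1 copies in the R64 gene table, at 1.78 ± 0.25. Both genes of the mitochondrial isocitrate dehydrogenase rose, IDH1 to 2.25 ± 0.27 and IDH2 to 2.12 ± 0.24. The drug resistance regulator gene PDR3 was 1.91 ± 0.23, AIM17 1.88 ± 0.29, RTC3 1.88 ± 0.27 and YIR043C 1.73 ± 0.26. The largest falls included SRP40 at -5.70 ± 0.24, MTL1 at -5.60 ± 0.25, SIM1 at -4.80 ± 0.29, the RNA helicase gene DRS1 at -4.12 ± 0.28, GSC2 at -3.90 ± 0.26 and OSW7 at -3.83 ± 0.24. All 4 alpha-mating-type markers fell, SAG1 to -2.85 ± 0.25, MF(ALPHA)2 to -1.51 ± 0.28, MF(ALPHA)1 to -1.45 ± 0.27 and STE3 to -1.34 ± 0.23, alongside the falls in glycolysis, zinc and uptake genes. The a-mating-type list was not called (median 0.58, or 1.10 as deposited, camera adjusted p = 0.121), and 0 of its 7 spots passed. Of the strain markers, LEU2 was 0.56 ± 0.28, GCN4 -0.81 ± 0.28, MET17 -0.84 ± 0.28, ADE2 -0.50 ± 0.43, URA3 -0.28 ± 0.29, LYS2 -0.24 ± 0.23 and HIS3 0.21 ± 0.24, none past the test, and ADE2 and URA3 changed sign between experiments.

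In total 270 spots passed limma's test in aft1aft2 against wt, 44 higher and 226 lower, of which 18 had no gene name, and 1302 had an unadjusted p under 0.05. At least 2-fold in both experiments were 326 spots, 64 higher and 262 lower, beside 21 that went opposite ways. As deposited these were 507, 413 higher and 94 lower. With the values as deposited the calls were 72, 36 higher and 36 lower. In that setting FTR1, TIS11, SMF3, PRY1, APE1, AKR1 and AIM17 no longer passed (adjusted p from 0.0544 for AIM17 to 0.118 for AKR1). With 1 hybridisation left out the calls were 125 and 90 without wt replicate 1 or 2, 75 without either aft1 replicate, 559 without aft1aft2 replicate 1 and 96 without aft1aft2 replicate 2. The excess of lower calls was absent without aft1aft2 replicate 1, where that strain rests on its replicate 2 membrane alone. That membrane had the widest spread of levels of all, with an SD of 0.512. On it, 69 spots were at least 4-fold brighter than in experiment 1 and 14 as much dimmer.

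**Figure D2:**
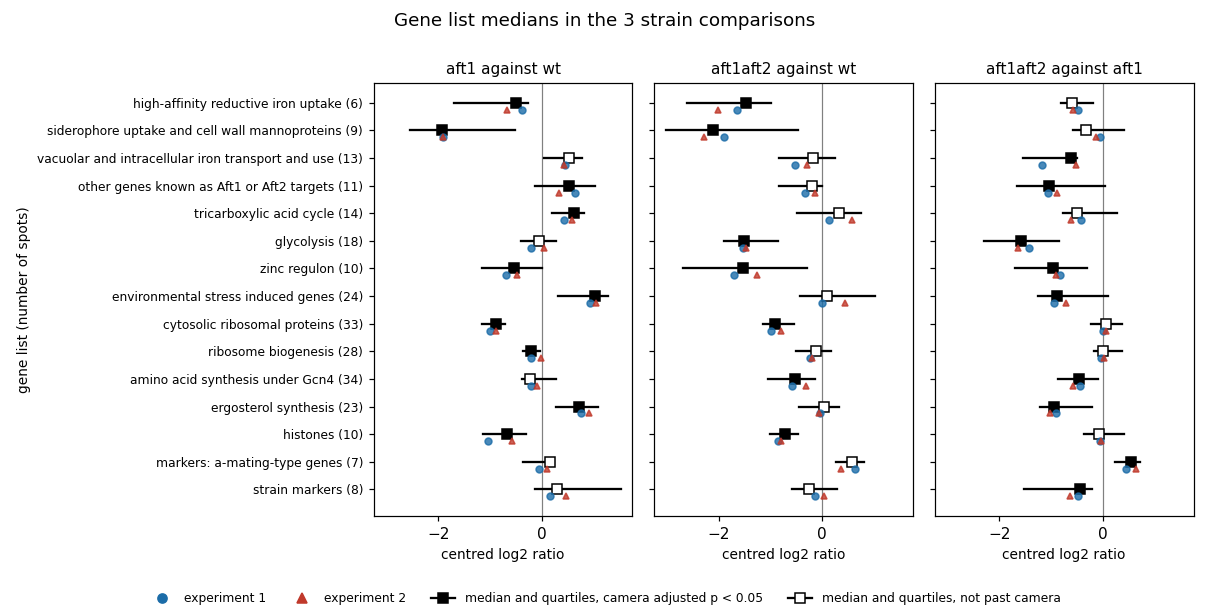
Median centred log2 ratio (x axis) of the 15 gene lists that camera called in at least 1 comparison (y axis, number of spots in brackets), as squares with lines from lower to upper quartile, filled where the camera adjusted p was under 0.05, and with the medians of experiments 1 and 2 as circles and triangles just below. Ribosomal proteins sit at -0.89 and -0.92 against wt in the mutants and at 0.0625 between them, while glycolysis sits at -0.05 in aft1 against wt and at -1.52 and -1.58 in the other comparisons.

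The direct comparison of aft1aft2 with aft1 asks, by the labels, what differs with the AFT2 deletion where AFT1 is mutated, although the spots of these genes do not check the labels. Of 13 genes for iron handling inside the cell 4 fell: SMF3 to -2.31 ± 0.27 (SE, n = 2), the mitochondrial iron carrier gene MRS4 to -1.85 ± 0.33, the vacuolar iron permease gene FTH1 to -1.76 ± 0.29 and TIS11 to -1.55 ± 0.26. APE1 at -2.59 ± 0.27, PRY1 at -2.25 ± 0.23 and AKR1 at -1.44 ± 0.24 fell with them. MRS4 and FTH1 did not pass the test in aft1aft2 against wt. MRS4 had stood at 1.66 ± 0.33 in aft1 against wt, also not past the test, so its fall may start from a raised level in aft1. Reductive and siderophore uptake genes did not pass the test, with FIT3 at -0.57 ± 0.29, ARN1 at -0.76 ± 0.32, ENB1 at -0.81 ± 0.24, FRE1 at -0.88 ± 0.25 and FTR1, just short of it, at -1.59 ± 0.29 (adjusted p = 0.0502). In experiments 1 and 2 FIT3 was -1.02 and -0.13, and ARN1 was -0.25 and -1.28. FIT2, FIT3 and FET3 already stood at -5.85, -3.37 and -3.43 in aft1 against wt. Signal over background is not in the values used here, so whether such spots could show a further fall is not known. Glycolytic genes and spots of the Ty1 retrotransposon fell strongly.

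Of the 13 vacuolar and intracellular genes 4 fell and 0 rose, against 5 lower and 1 higher adjusted over the list alone. Their median was -0.61, with a camera adjusted p of 0.000425 (adjusted p = 0.299 with an estimated correlation). It was -1.17 without replicate 2, -0.51 without replicate 1 and -0.36 with the values as deposited. Of the 11 other known targets 3 fell, and 6 did adjusted over the list alone, while ECM4 at -1.89 ± 0.40 did not pass. Their median was -1.03, with a camera adjusted p of 0.00266 (adjusted p = 0.299 with an estimated correlation). Of the 6 reductive uptake genes 0 passed limma's test, against 2 lower at an unadjusted p under 0.05 and 2 adjusted over the list alone. CCC2 was -0.58 ± 0.49 and FRE2 -0.61 ± 0.42, and both changed sign between experiments (0.17 and -1.34, and -1.39 and 0.16). The list median was -0.60, or -0.35 as deposited (camera adjusted p = 0.107). Of the 9 siderophore and mannoprotein genes 0 passed, against 1 higher and 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. FRE3 was 0.90 ± 0.28 (list median -0.32, or -0.07 as deposited, camera adjusted p = 0.785).

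Of 18 glycolytic genes 11 fell, and 15 did adjusted over the list alone, among them TDH1 at -3.26 ± 0.25, ENO1 at -2.86 ± 0.29, PGK1 at -2.63 ± 0.24 and GLK1 at -2.46 ± 0.26. The list median was -1.58, with a camera adjusted p of 1.98e-13 (adjusted p = 0.299 with an estimated correlation). Of 23 ergosterol genes 4 fell, ERG13, ERG27, ERG3 and ERG25 at -1.78 to -1.50, against 16 lower and 1 higher adjusted over the list alone. Their median was -0.94, with a camera adjusted p of 2.66e-06 (adjusted p = 0.299 with an estimated correlation). Against wt the ergosterol median was 0.72 in aft1 and 0.05 in aft1aft2, or 0.56 as deposited in the latter. Camera did not call the list in aft1aft2 against wt (adjusted p = 0.785). Of 24 stress genes 6 fell, GLK1, SSA4 at -2.20 ± 0.24, HXK1, HSP26, PNC1 and TPS2, against 14 lower and 2 higher adjusted over the list alone. Their median was -0.88, with a camera adjusted p of 0.000132 (adjusted p = 0.299 with an estimated correlation). Of 10 zinc regulon genes 3 fell, ZRT1 and ZPS1 each at -2.11 ± 0.23 and ZRT3 at -1.84 ± 0.24, and 6 did adjusted over the list alone. Their median was -0.97, with a camera adjusted p of 0.000105 (adjusted p = 0.299 with an estimated correlation). The 34 amino acid synthesis genes had a median of -0.47 with 1 fall, SER3 at -3.06 ± 0.30, and 7 adjusted over the list alone (camera adjusted p = 0.000348, and adjusted p = 0.299 with an estimated correlation). As deposited that median was -0.22. Ribosomal protein genes had a median of 0.0625, or 0.32 as deposited, with 0 of 33 past limma's test, 0 adjusted over the list alone, and a camera adjusted p of 0.785. The a-mating-type markers lay higher as a list with a median of 0.54 and 0 of 7 past the test (camera adjusted p = 0.0317, and adjusted p = 0.393 with an estimated correlation), and 0 of the 4 alpha-mating-type markers passed.

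Among the 10 largest falls, 7 were Ty1 reading frames: YAR010C at -3.90 ± 0.23, YJR028W at -3.78 ± 0.24, YBL005W-A at -3.72 ± 0.25, YJR026W at -3.64 ± 0.26, YBR012W-A at -3.63 ± 0.23, YMR051C at -3.58 ± 0.25 and YBR012W-B at -3.54 ± 0.26. These are near-identical copies, so no single element can be assigned. The others were the purine synthesis gene ADE17 at -3.99 ± 0.26, the serine hydroxymethyltransferase gene SHM2 at -3.42 ± 0.24 and the cell wall protein gene HSP150 at -3.36 ± 0.23. Rises were smaller: the DNA helicase gene CHL1 at 1.92 ± 0.27, FRK1 at 1.82 ± 0.29, SPL2 of phosphate regulation at 1.70 ± 0.27, YDL241W at 1.69 ± 0.31, and LEA1 at 1.59 ± 0.29. Next came RGI2 at 1.55 ± 0.23, DNA2 at 1.48 ± 0.27, the kinetochore gene CBF2 at 1.41 ± 0.24, HST2 at 1.38 ± 0.23 and CTR1 at 1.34 ± 0.23. Of the strain markers, LEU2 fell to -1.66 ± 0.28, while ADE2 at -1.96 ± 0.43, MET17 at -1.48 ± 0.28, GCN4 at -0.50 ± 0.28, TRP1 at -0.38 ± 0.31, LYS2 at -0.21 ± 0.23, URA3 at -0.21 ± 0.29, which changed sign between experiments, and HIS3 at 0.50 ± 0.24 did not pass. Their list had a median of -0.44, or -0.19 with the values as deposited (centred camera adjusted p = 0.0384, and adjusted p = 0.506 with an estimated correlation).

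In total 172 spots passed limma's test in aft1aft2 against aft1, 14 higher and 158 lower, of which 10 had no gene name, and 1372 had an unadjusted p under 0.05. At least 2-fold in both experiments were 285 spots, 49 higher and 236 lower, beside 5 that went opposite ways. As deposited these were 265, 116 higher and 149 lower. With the values as deposited 52 passed, 2 higher and 50 lower. Named genes that no longer passed were MRS4, FTH1, TIS11, AKR1, LEU2, CHL1, FRK1, SPL2, YDL241W, LEA1, DNA2, CBF2, HST2 and CTR1 (adjusted p from 0.0573 for SPL2 to 0.128 for TIS11). With 1 hybridisation left out the calls were 14 and 13 without aft1 replicate 1 or 2, 503 and 90 without aft1aft2 replicate 1 or 2, and 256 without either wt replicate. The excess of lower calls was again absent without aft1aft2 replicate 1, where that strain rests on its replicate 2 membrane, the one with the widest spread of levels.

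Comparisons that share hybridisations also share their errors. Chance overlap was therefore also simulated without effects for lists of the same sizes, a test chosen after seeing the data. Of the 38 spots lower in aft1 against wt, 37 were also lower in aft1aft2 against wt, with 16.3 simulated and 1.41 for independent lists. Of the 51 higher spots 10 were higher in both, near the 8.72 simulated, with 0.369 for independent lists. The simulated lists held the smallest p-values without a threshold, and simulated calls at the threshold shared 0.02 spots. Taken from different experiments, 41 and 39 spots were at least 2-fold higher in both, with 28.0 and 12.6 for independent lists. Spots at least 2-fold higher in aft1 and lower in aft1aft2 also exceeded independent lists, at 34 and 42 with 22.9 and 24.8. The reverse pair, lower in aft1 and higher in aft1aft2, stayed below them, at 18 and 7 with 30.8 and 11.9. An excess over independent lists therefore does not decide whether shared error accounts for the shared rises. A further 13 spots were higher in aft1 and lower in aft1aft2 than in wt, with 0.29 simulated and 1.89 for independent lists, but 0 of these were so with the values as deposited. Across spots the ratios of both mutants to wt correlated with r = 0.449, below the 0.501 simulated without any effect. Their covariance of 0.165 exceeded the simulated 0.0463 by 0.118. With the ratios taken from different experiments, which share no hybridisation, r was 0.187 and 0.218. Of the 51 spots higher in aft1 against wt, 33 were lower in aft1aft2 against aft1, with 16.6 simulated and 1.32 for independent lists. For this pair r was -0.400 with a simulated -0.499, the covariance was -0.143 with a simulated -0.0461, and r was -0.241 and -0.292 across experiments. Part of these overlaps may come from the shared hybridisations.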

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

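The tests of explanation in this part were chosen after the results had been seen. In all, 13 spots were past limma's test in opposite directions in the mutants, higher in aft1 and lower in aft1aft2 than in wt, and past the direct test of the difference between them. In settings chosen after seeing the data, 0 of the 13 did so with the values as deposited or without any 1 wt or aft1 hybridisation, 3 without aft1aft2 replicate 2, 12 without aft1aft2 replicate 1, 10 with columns scaled, 12 quantile normalised and 11 with a robust prior. The opposite calls thus depend on the centring and also on having both replicates of wt and of aft1. With 1 hybridisation left out the Ty1 medians stayed between 1.60 and 1.78 in aft1 and between -1.61 and -1.34 in aft1aft2 against wt, so where calls ended the folds had changed little, with 1 residual degree of freedom. Of the 13, 12 were reading frames of the retrotransposon Ty1. In aft1aft2 against aft1 YAR010C was -3.90, YJR028W -3.78, YBL005W-A -3.72, YJR026W -3.64, YBR012W-A -3.63, YMR051C -3.58 and YBR012W-B -3.54. YML040W was -3.30, YJR027W -2.91, YBL005W-B -2.86, YJR029W -2.81 and YML039W -2.75. The remaining spot, of the cell wall protein gene HSP150, was -3.36, from 2.03 in aft1 against wt and -1.33 in aft1aft2 against wt.

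The 18 Ty1 spots had medians of 1.72 in aft1 against wt (15 called higher), -1.45 in aft1aft2 against wt (13 called lower) and -3.03 in aft1aft2 against aft1 (18 called lower). As deposited they were 1.98 (15 called), -0.93 (0 called) and -2.77 (17 called), so the fall against wt is uncertain. A single deviating aft1 hybridisation is argued against by the Ty1 median in the experiment with the smaller rise, 1.63 with 1.84 in the other. Whether many spots read 1 change through shared sequence was weighed with the Ty2 spots. In aft1aft2 against aft1 the 2 Gag-Pol spots had a median of -2.47 and the 2 Gag spots -0.32, a difference of -2.15. That difference would fit shared reading only if Ty2 Gag-Pol is closer to Ty1 than Ty2 Gag is. Sequences were not compared here, so these few spots do not decide it. The number of Ty1 spots should not be read as a count of separate events, and which element changed stays open. The strain difference the design names remains among the open explanations, untested beyond these samples, as does a difference in Ty1 copies between the strains.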

How the results depend on the processing

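Of the calls reported, 0 changed sign in any comparison with the values as deposited, scaling, quantile normalisation or any hybridisation left out. The same held for the experiment block and a robust prior, which alter the error of a value and hardly or not the value itself. As deposited, every spot of a comparison moves by the same amount, which is smaller than the called values named above. The 0 thus says little about robustness. Numbers of calls are given for aft1 against wt, aft1aft2 against wt and aft1aft2 against aft1, which were 89, 270 and 172; where a number moved by over 1.5 times the cause was not tested unless stated. With the values as deposited they were 58, 72 and 52, of which 57, 69 and 52 were calls of the fit reported. With 1 residual degree of freedom from the 2 columns of a comparison they were 44, 157 and 112. Scaling gave 217 and quantile normalisation 213 in aft1 against wt, with all 89 kept in both, and stayed within 1.5 times in the others. At an adjusted p of 0.1, which by construction admits more, they were 244, 513 and 445. The replicate block of experiment number, fitted to the 6 columns, gave 408, 787 and 774; it treats dependent columns as independent, as does the fit of the 6 columns without a block, chosen after seeing the data, with 278, 477 and 399. Ratios are formed within an experiment, so the fit reported already holds the experiment as a term. A robust prior gave 88, 254 and 161.

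Leaving out 1 hybridisation at a time, also chosen after seeing the data, gave 4 to 233 calls in aft1 against wt, 75 to 559 in aft1aft2 against wt and 13 to 503 in aft1aft2 against aft1, with 1 residual degree of freedom and a lone membrane assumed to vary like the others. The lowest numbers came without aft1 replicate 2 (4, 75 and 13) or aft1 replicate 1 (7, 75 and 14), the highest without aft1aft2 replicate 1 (233, 559 and 503), and aft1aft2 replicate 2 left out gave 233, 96 and 90. Without wt replicate 1 they were 48, 125 and 256, and without wt replicate 2 38, 90 and 256. Leaving out a whole experiment leaves no residual degrees of freedom, so for named genes and lists it gives values with no test.

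Spots past a fold in both experiments numbered 717, 901 and 933 at 1.5-fold and 68, 90 and 94 at 3-fold, by construction of the threshold, against 239, 326 and 285 at 2-fold; as deposited there were 306 (253 higher), 507 (413 higher) and 265 (116 higher). With an estimated correlation camera called 0, 0 and 0 lists, where it had called 10, 7 and 9. Camera has little power in that setting, with 2 residual degrees of freedom. As deposited it called 8, 8 and 9, scaled 10, 7 and 9, and quantile normalised 11, 7 and 9, the last 2 settings added after seeing the data. The ribosome biogenesis list, at -0.20 in aft1 against wt (camera adjusted p = 0.0366, and adjusted p = 0.386 with an estimated correlation), was -0.02 without replicate 1 and turned to 0.0625 with the values as deposited, where the call was lost (adjusted p = 0.0593); the cause of the turn was the shift of the column medians. Of 132 named values, 98 kept direction and side of the threshold as deposited, 26 no longer passed and 8, none of them called, changed sign. For single genes, lists and the opposite calls together, 463 alternatives kept the result, 54 lost the call, 44 moved and 1 reversed. For named genes with 1 experiment left out, keeping the result meant only the same sign. The rule that named the largest changes had already required that sign in both experiments. Every list call was lost with an estimated correlation, so these totals do not measure how robust the results are. Combining direct and indirect estimates was not run because closure makes it identical to the fit reported, and a filter on missing values was not run because there were none. The signal over background of each spot, which limits dim spots, is not in the values used here.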

Other observations

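The lists and tests in this part were chosen after the data had been seen, except the test of reading-frame length. The gene lists added here were built from genes seen to move, so camera tests them on genes chosen for the pattern, and no p below decides whether a list moved. Genes of phospholipid synthesis that respond to inositol and choline were low in aft1aft2 against wt, with 7 of 15 past limma's test: OPI3 at -3.19 ± 0.28 (SE, n = 2), the inositol transporter gene ITR1 at -3.06 ± 0.29, the inositol synthesis gene INO1 at -2.47 ± 0.29, HNM1 at -2.22 ± 0.24, CHO1 at -1.77 ± 0.27, FAS2 at -1.73 ± 0.33 and CDS1 at -1.22 ± 0.24. In aft1 against wt 2 of them fell, INO1 at -2.30 ± 0.29 and ITR1 at -1.83 ± 0.29. The list median was -1.21 in aft1aft2 against wt (camera adjusted p = 0.152 with an estimated correlation), -0.61 in aft1 against wt and -0.59 in aft1aft2 against aft1, where 2 fell. As deposited these were -0.69, -0.35 and -0.34. Genes of purine and one-carbon metabolism were low in aft1aft2 against aft1, with 5 of 17 spots past the test: ADE17 at -3.99 ± 0.26, SHM2 at -3.42 ± 0.24, GCV3 at -2.03 ± 0.27, MTD1 at -1.54 ± 0.23 and ADE13 at -1.50 ± 0.25. Their median was -0.59, or -0.34 as deposited (camera adjusted p = 0.152 with an estimated correlation). It was 0.56 in aft1 against wt with 0 past limma's test, and -0.50 in aft1aft2 against wt with 2 lower, or 0.02 with the values as deposited.

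Cell wall protein genes went both ways in aft1 against wt, with a list median of 0.69. SED1 at 2.01 ± 0.23 and HSP150 at 2.03 ± 0.23 were higher and CWP1 at -1.50 ± 0.24 lower. In aft1aft2 against aft1 5 of 17 were lower, among them ECM33 at -2.47 ± 0.23 and PIR1 at -1.99 ± 0.24. The median there was -1.14 (camera adjusted p = 0.201 with an estimated correlation). In aft1aft2 against wt 6 of 17 were lower, but the median was -0.14, or 0.38 with the values as deposited. Folding factors of the endoplasmic reticulum were low in aft1aft2 against wt for 4 of 13 spots, KAR2 at -2.10 ± 0.35, PDI1 at -1.88 ± 0.25, EUG1 at -1.60 ± 0.27 and LHS1 at -1.31 ± 0.25, with a median of -0.51, or 0.005 with the values as deposited (camera adjusted p = 0.342 with an estimated correlation). It was -0.03 in aft1 against wt and -0.39 in aft1aft2 against aft1, with 0 and 2 lower, or 0.23 and -0.14 as deposited. Beside SRP40 and MTL1, the spots of ASF1 at -2.92, CAB3 at -2.95, DRS1 at -3.05, SIM1 at -2.82 and SIS2 at -2.11 were low in aft1 against wt. In aft1aft2 against wt ASF1 was -3.63, CAB3 -2.49, DRS1 -4.12, SIM1 -4.80 and SIS2 -2.17. Sequence shared between these spots, or those of FIT2, FIT3 and RFM1, and other transcripts was not examined here.

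The glycolysis median of -1.58 in aft1aft2 against aft1 was weighed against 3 technical explanations. The ribosomal protein genes did not go with a compression of the signal of all abundant transcripts, with a median of 0.0625 (0.32 as deposited) and quartiles of -0.23 and 0.38. A list of elongation factors and abundant chaperones did go with glycolysis, at a median of -1.22, so these lists do not decide on compression. In aft1aft2 against wt all 3 lists were low: glycolysis at -1.52, elongation factors and chaperones at -1.22 and ribosomal proteins at -0.92. Ribosomal proteins were already at -0.89 in aft1 against wt. A trend with reading-frame length is argued against because its removal left the glycolysis median at -1.53. Over 5523 named spots the rho between ratio and length was -0.125. A single deviating hybridisation is argued against by a median of -1.43 in the experiment with the smaller fall. As a hypothesis, glycolytic transcripts may depend on the strain difference that the labels name, which stays untested outside these samples, and the brightness of the spots was not in the values. A difference between the strains in culture or RNA preparation was not tested, since the experiments may not be separate cultures.

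The AFT2 spot, higher by 2.07 in experiment 2 than in experiment 1 in aft1aft2 against the other strains, goes against its label. That wt or aft1 was on the aft1aft2 membrane of experiment 2 is argued against: of 205 spots at least 2-fold lower than in both strains in experiment 1, 88.3% were lower than in wt and 91.7% than in aft1 in experiment 2. Of all spots 49.6% were lower than in aft1, a share set by the centring, and of 59 spots higher in experiment 1, 74.6% and 76.3% were higher again, while a strain from outside the series was not tested. Isolated bright spots on that membrane are a candidate explanation. The values cannot separate it from a skew across the membrane, since positions and brightness of spots were not available. By the ratios, 69 spots were at least 4-fold brighter in experiment 2 than in experiment 1 and 14 as much dimmer, a ratio of 4.93. For wt these numbers were 21 and 18, and for aft1 6 and 11. What lies behind the AFT1 and AFT2 values in experiment 1 stays open, since the sequence on these spots was not compared here.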
